A study of Arabidopsis thaliana with 12 samples.

How the data were processed

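Transcript levels were measured in dark-grown Arabidopsis thaliana seedlings of the Columbia accession on 12 single-colour oligonucleotide arrays. The 3 genotypes were wild type, ein2 and ein5. EIN2 is a membrane protein of the ethylene pathway whose loss makes seedlings insensitive to the gas. The series title describes EIN5 as an exoribonuclease. Each genotype was sampled in air and after ethylene, which gave 6 groups of 2 arrays, and the groups and replicate numbers come from the sample titles. All of these titles end in polyA. The exposure, per the series text, was 4 h of ethylene at 10 ppm.

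The labels disagree in places. The series text and the text of 1 sample, ein2 in air replicate 1, describe 3 days in the dark at 24 °C, whereas the texts of the other 11 samples describe 5 days at 25 °C. The extraction protocol speaks of mature leaves although the other labels speak of seedlings. No label says that the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

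The deposited table holds an intensity for each of 22746 probe sets on a linear scale. Per the labels' protocols, GeneChip Suite 3.2 and GeneSpring 4.2 were used by the authors. The mean of the deposited intensities after trimming 2% of the values at each end was 2480.3 to 2487 in all arrays, so the values had been scaled to a common trimmed mean before deposit, a step not given in the sources used here. The series text describes a division by the median of the values above 10 of each sample, which the deposited values do not show, since their array medians were 922 to 1039. The array medians of the log2 values spanned 0.17, above a limit of 0.1 set beforehand. Each array was therefore divided by the median of its values above 10, as in that description, and multiplied by the mean of those medians, with factors of 0.949 to 1.07. An offset of 16 was added and the log2 taken, which understates changes of dim probe sets. Levels are printed as scaled intensities without the offset. Between 3.75% and 5.98% of the values of an array lay at or under the offset. The table held 0 control probe sets, so a planned check of RNA quality from the ratio of 3' to 5' control signals was not possible.

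A table of the platform's annotation gave exactly 1 gene for 13513 probe sets and several genes for 503, from which no gene was named. The remaining 8730 were not listed there and are unnamed here, not without a gene. Of the single-gene probe sets 13436 matched the gene table of the TAIR10.1 assembly, which gave 13355 different genes, and 11933 of the probe sets carried only a locus number as their name. EIN2, EIN5, EBF1 and EBF2 were not among the genes named, so the planned values of these genes, and with them a check of the genotype labels on the mutated genes, are not reported here.

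Differences were tested with limma 3.58.1 in R 4.3.3. The 6 group means were fitted to all 12 arrays, since 2 arrays per group alone leave too little to estimate the spread, with moderated variances that follow the mean intensity. Each probe set had 6 residual degrees of freedom, and the prior added 7.89. The 11 comparisons were ethylene against air in each genotype, the 3 differences of those responses between genotypes (interaction contrasts), and 5 comparisons of genotypes within air or within ethylene. Tests were two-sided. Adjusted p is Benjamini-Hochberg over all probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. The ± after a log2 change is its standard error from this fit, and the ± after a level is the SD of the 2 arrays. The ± in the part on flagged results is explained there. The median standard error was 0.23 for a difference of 2 groups and 0.32 for a difference of responses. The number of arrays limits the precision: an exact permutation test of 2 arrays against 2 has too few regroupings to reach 0.05.

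On simulated data made from the levels and spread of these arrays, 60 of 100 probe sets changed by 1 log2 unit and 79 of 100 changed by 2 units were called in the comparison of ethylene with air in wild type. There, 12 of 151 calls (7.95%) were probe sets without a change. All simulated arrays had the same spread per probe set, whereas the real wild-type replicates differed more than the mutant ones. The median log2 difference between replicates was 0.32 for wild-type ethylene and 0.25 for wild-type air, against 0.19 to 0.21 for the mutant groups. These shares may therefore be too favourable for this comparison. A simulated list with a shift had an adjusted p of 1.55e-16, and 0 of 100 lists without a shift were called by camera, with 1 of them at an unadjusted p under 0.05. The simulated probe sets varied independently of each other and the lists were drawn at random. False calls of lists whose genes vary together were therefore not tested.

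Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, with an estimated correlation as the alternative. Each gene entered with its brightest probe set, and p was adjusted over the lists of a comparison. The 17 fixed lists covered the ethylene pathway, textbook ethylene-induced genes, ethylene biosynthesis, ERF transcription factors, microRNA targets, RNA decay, auxin, gibberellin, cell wall expansion, photosynthesis, defence and jasmonate, root hairs, seed storage and late embryogenesis, floral organs, rapid stress and touch, low oxygen, and reference genes. Of these, 12 had at least 2 measured and named members and were tested. That minimum was set after the matches had been counted. Measured and named were 3 of 28 textbook ethylene-induced, 2 of 16 pathway and 7 of 66 microRNA target genes. For RNA decay the number was 7 of 24, for auxin 7 of 22 and for cell wall expansion 7 of 23. It was 2 of 15 for gibberellin, 2 of 25 for photosynthesis, 2 of 16 for root hairs and 2 of 14 for rapid stress. For defence and jasmonate it was 3 of 15, and for reference genes 3 of 12. Results of a list below cover only its measured and named members. For the 3 lists with 1 such member its value is given, and the lists of seed storage markers and of floral organ markers had 0, so they have no result. A further 5 lists were written after the leading genes had been seen: late embryogenesis abundant (LEA) proteins, seed storage with oil body and seed cupin genes, root hair specific genes, GDSL lipases, and class III peroxidases. Their tests describe these arrays and are not independent evidence.

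The comparisons, the tests, the rule for named genes, the scaling rule, the 17 lists and the alternatives were fixed before the data were examined. The genes named in each comparison are the 10 largest rises and 10 largest falls among called probe sets with 1 gene, groups that do not overlap, and a mean in the higher group above the median of all probe sets. For differences of responses the overlap of groups does not apply. Up to 4 members of each list with the smallest p are added. Among these, the text prefers genes whose call held when any 1 array was left out. The alternatives were quantile normalization, offsets of 1 and 64, removal of probe sets below the 40th percentile of mean level, variances without a trend, a fit of the compared groups alone, the replicate number as a block, array weights, and leaving out each array in turn. For the lists, averaging all probe sets of a gene was also tried. Values as deposited, and a fit of each mutant in air against 1 of the wild-type air arrays, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.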

Results

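Transcript profiles were collected from 12 arrays of dark-grown seedlings, 2 for each of 6 groups: wild type, ein5 and ein2, each in air or after 4 h of ethylene. Single arrays are named here by genotype, gas and replicate number. The deposited median intensity of an array lay between 922 and 1039, and the correlation of an array with its own replicate across probe sets lay between 0.960 and 0.975. The mean correlation of an array with those of other groups was nearly as high, between 0.947 and 0.965. Wild-type ethylene 1 correlated at 0.9598 with its replicate and at 0.9604 on average with the other groups. The median difference between the 2 arrays of a group was 0.32 on the log2 scale for wild-type ethylene and 0.25 for wild-type air, against 0.19 to 0.21 for the 4 mutant groups. All changes below are log2 changes with their standard error, and calls are from the limma fit with Benjamini-Hochberg adjustment over 22746 probe sets.

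The first question was which transcripts changed within 4 h of ethylene in wild-type seedlings. RTE1, which encodes a regulator of the ethylene receptor ETR1, rose from a level of 2763 ± 211 to 10753 ± 285 (SD, n = 2), a change of 1.96 ± 0.12, adjusted p = 1.6e-07. The organ-size gene ARL rose from 7943 ± 54.2 to 23757 ± 2587 (1.57 ± 0.12, adjusted p = 1.27e-06). IAGLU, which encodes a glucosyltransferase of the auxin indole-3-acetic acid, rose by 2.73 ± 0.16, adjusted p = 1.26e-07. Among genes of cell wall enzymes, GH9B12 of glycosyl hydrolase family 9 rose by 3.08 ± 0.25, adjusted p = 3.08e-06, and the xyloglucan endotransglucosylase gene XTH26 by 2.78 ± 0.43, adjusted p = 0.00075. The largest rise among the genes named by the rule was that of AT5G40590, from 226 ± 43.3 to 8877 ± 108 (5.21 ± 0.22, adjusted p = 5.79e-09), and the class III peroxidase genes AT5G19890 and AT1G49570 rose by 4.34 ± 0.22 and 3.59 ± 0.20. SWEET17, which encodes a vacuolar fructose transporter, fell from 5409.6 ± 1307 to 828 ± 323 (-2.72 ± 0.22, adjusted p = 2.57e-06). HOS3-1 fell by 3.43 ± 0.37 and AT5G13900 fell by 3.35 ± 0.14. In all, 2298 probe sets were called, 869 higher and 1429 lower, of which 268 and 497 changed over 2-fold. The called probe sets with 1 gene numbered 435 higher and 729 lower. The number of calls was 1323 when the variances followed no trend with intensity, 1309 with array weights and 813 when only the 4 wild-type arrays were fitted. The split was 1366 higher and 1480 lower without wild-type ethylene 1, and 536 and 1436 without wild-type ethylene 2.

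Of the fixed gene lists, 2 of 12 were called in this comparison, with 3 at an unadjusted p under 0.05. The textbook ethylene-induced genes rose together (camera, adjusted p = 1.15e-05, and adjusted p = 0.0309 with an estimated correlation), with a median change of 1.57. Of the 28 genes of that list only 3 were measured and named. RTE1 and ARL were called over all genes, and all 3 when adjusted over the list alone. The defensin gene PDF1.2 was not called over all genes (1.54 ± 0.66, adjusted p = 0.179). The ethylene pathway list was called with 2 members at an adjusted p of 0.0343, but adjusted p = 0.196 with an estimated correlation, 0.0603 after quantile normalization, 0.0539 without wild-type air 2 and 0.155 without wild-type ethylene 2. It rested on RTE1, since EIN3, the central transcription factor of the pathway, lay at 12394 ± 158 in air and 12696 ± 2053 in ethylene (0.03 ± 0.12, adjusted p = 0.943). RTE1 is a member of the textbook list too, so the calls of these lists, here and below, are not independent. The ethylene biosynthesis list held AT1G12010 alone, an ACC oxidase gene, which fell from 1873 ± 241 to 685 ± 174 (-1.45 ± 0.21, adjusted p = 0.000435). Neither ORA47, the only measured and named member of the ERF list (0.19 ± 0.57, adjusted p = 0.907), nor AT4G17260, alone in the low oxygen list (0.15 ± 0.12, adjusted p = 0.529), was called.

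The remaining fixed lists were not called in wild type. Of the 7 auxin genes, IAA20 of the Aux/IAA family rose from 1170.4 ± 232 to 3441 ± 262 (1.55 ± 0.19, adjusted p = 8.4e-05) and 1 fell, or 1 and 3 when adjusted over the list alone (list adjusted p = 0.72, median -0.21). Of the 7 cell wall expansion genes 1 rose and 2 fell, or 2 and 2 when adjusted over the list alone (list adjusted p = 0.72, median -0.05); the expansin gene EXPA8 fell from 19898 ± 1828 to 8809.8 ± 1832 (-1.19 ± 0.14, adjusted p = 7.99e-05). None of the 7 microRNA target genes was called by limma and 3 were lower when adjusted over the list alone (list adjusted p = 0.334, median -0.11). None of the 7 RNA decay genes was called either (list adjusted p = 0.72, median -0.09); at an unadjusted p under 0.05 the counts were 3 and 1. The gibberellin list had 1 of 2 members lower (list adjusted p = 0.619, median -0.23). The photosynthesis list had 1 of 2 higher (list adjusted p = 0.292, median 0.47, and called at 0.0442 without wild-type ethylene 1). The root hair list had 1 of 2 higher (list adjusted p = 0.165, median 0.56, and called at 0.0252 without wild-type air 1). For defence and jasmonate the list adjusted p was 0.334 with a median of 0.90 over 3 genes, and for reference genes 0.502 with 0.21 over 3, with 0 members of either called and 1 and 1 at an unadjusted p under 0.05. The rapid stress list had 1 of 2 members higher; its test pointed up (adjusted p = 0.619) while its median and mean were both -0.04.

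Larger families were examined after the leading genes had been seen. Of 72 genes of GDSL lipases, 14 fell and 1 rose in wild type (adjusted p = 0.00228, and adjusted p = 0.325 with an estimated correlation), among them AT1G75900, which fell from 12577 ± 1768 to 1510.2 ± 6.17, AT1G29660, which fell by 3.01 ± 0.14, and AT3G50400, which fell by 2.56 ± 0.18. Of 36 genes of late embryogenesis abundant (LEA) proteins, known from maturing and dry seed, 10 fell and 2 rose (adjusted p = 0.00216, and adjusted p = 0.325 with an estimated correlation), with AT5G66780 and LEA18 at -2.05 ± 0.23 and -1.41 ± 0.19. Class III peroxidase genes went both ways, 8 higher and 6 lower of 55 (adjusted p = 0.367, or 0.039 without wild-type air 1); their test pointed up with a median of -0.03 and a mean of 0.09.

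**Figure D1:**
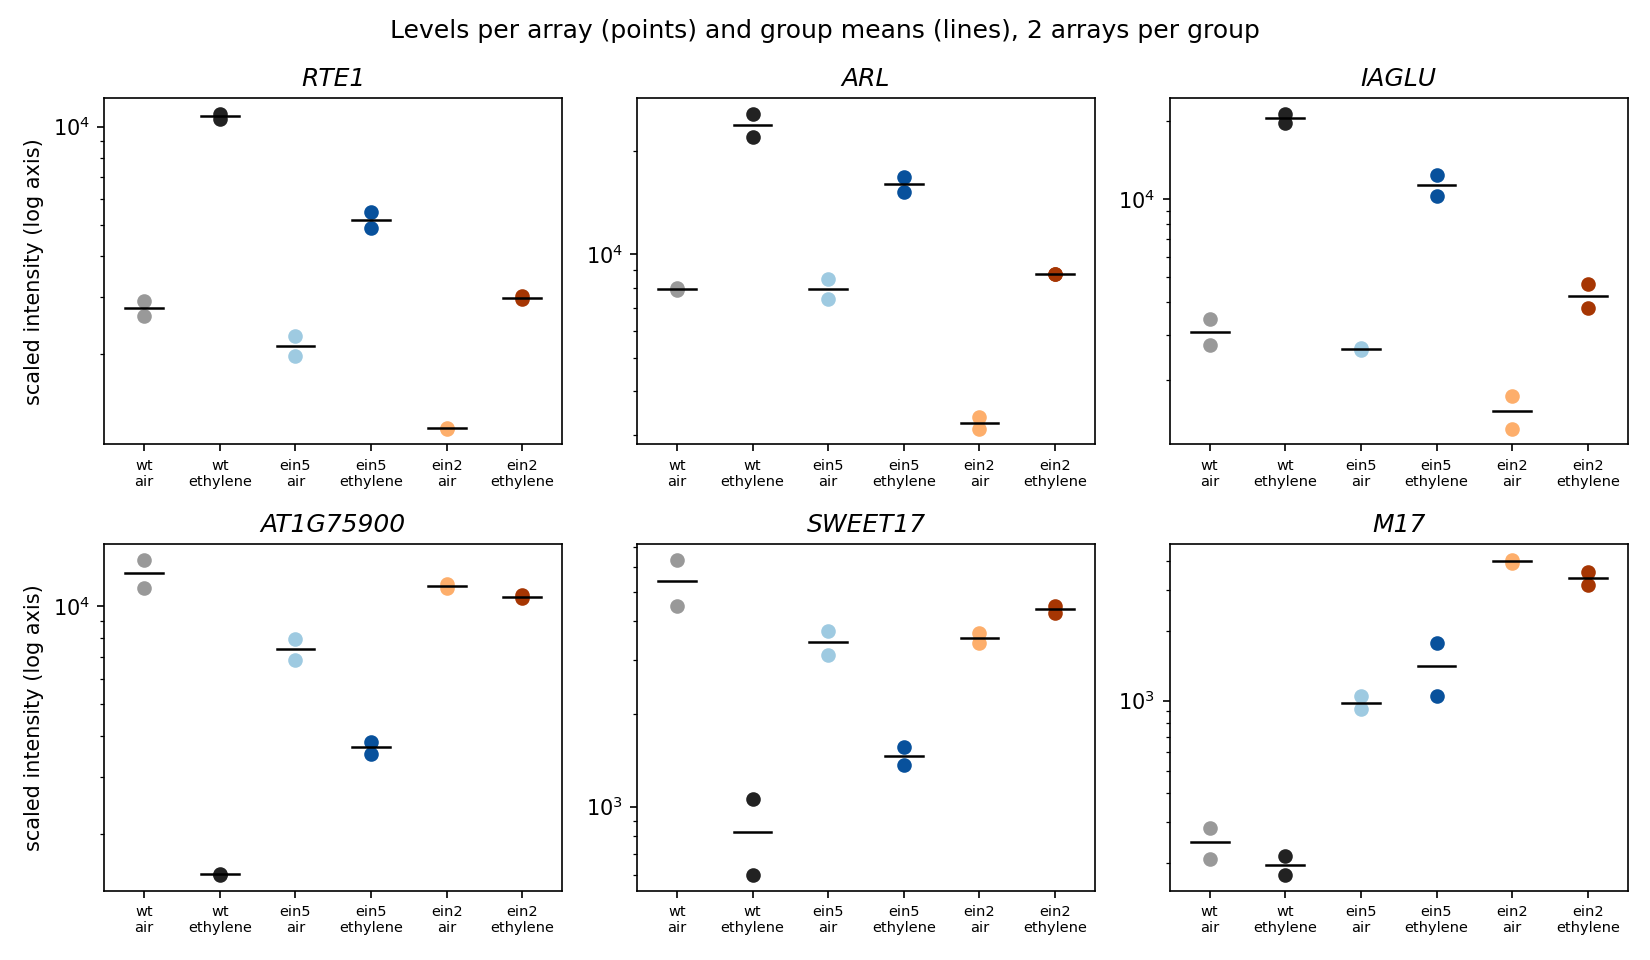
Scaled intensity (log axis) of RTE1, ARL, IAGLU, AT1G75900, SWEET17 and M17 in the 6 groups; each point is 1 array and each line the mean of the 2 arrays of a group. RTE1 rose in each genotype on ethylene, to 10753 in wild type, 5175 in ein5 and 2980.2 in ein2, whereas AT1G75900 fell to 1510.2 in wild type and 3693 in ein5 and lay at 10686 in ein2.

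The same question was asked of ein5, a mutant of an exoribonuclease. RTE1 rose from 2122 ± 219.7 to 5175 ± 419.9 (1.28 ± 0.12, adjusted p = 7.24e-05) and ARL from 7929.5 ± 747 to 15961 ± 1169 (1.01 ± 0.12, adjusted p = 0.000431). IAGLU rose by 2.09 ± 0.16, GH9B12 by 1.93 ± 0.25 and CYP718, a cytochrome P450 gene, by 3.46 ± 0.31 from 119.9 to 1384. AT2G39980 rose from 3074 ± 59.4 to 23531 ± 1516 (2.93 ± 0.14, adjusted p = 1.07e-07). AT5G48490 fell by 2.24 ± 0.18, adjusted p = 2.67e-05, MSRB6, which encodes a methionine sulfoxide reductase, fell by 1.87 ± 0.27, adjusted p = 0.00261, and AT1G75900 fell by 1.00 ± 0.12, adjusted p = 0.000589. In ein5, 369 probe sets were called, 176 higher and 193 lower, of which 83 and 93 had 1 gene. Of 12 lists 3 were called: textbook ethylene-induced genes (adjusted p = 1.1e-06, and 0.02 with an estimated correlation), the ethylene pathway (adjusted p = 0.0164, but adjusted p = 0.144 with an estimated correlation) and the 2 root hair expansin genes (adjusted p = 0.0325, but adjusted p = 0.351 with an estimated correlation). The called pathway gene was RTE1, which also belongs to the textbook list. Members called over all genes numbered 2 of 3 textbook, 1 of 2 pathway and 0 of 2 root hair genes, and 2, 1 and 2 when adjusted over the list alone. The adjusted p of the root hair list was 0.118 without ein5 air 1, 0.0939 without ein5 ethylene 1 and 0.0551 without ein5 ethylene 2. Of the GDSL lipase genes 7 fell and 0 rose (adjusted p = 1.68e-05, but adjusted p = 0.136 with an estimated correlation). The number of calls fell to 127 and 112 without ein5 air 1 or 2 and to 106 and 125 without ein5 ethylene 1 or 2, and was 576 and 565 without wild-type ethylene 1 or 2. It was 50 without a variance trend and 867 with array weights. The majority turned to 247 higher and 221 lower after quantile normalization, 202 and 175 with values as deposited, 29 and 21 without a variance trend, 167 and 164 when only the compared groups were fitted and 85 and 42 without ein5 air 1, and it also turned on leaving out any ein2 array, ein5 air 2 or ein5 ethylene 1.

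In ein2, known as insensitive to ethylene, a set of transcripts also rose on the gas. RTE1 rose from 1180.4 ± 1.95 to 2980.2 ± 51.3 (1.32 ± 0.12, adjusted p = 4.79e-05) and ARL from 3243 ± 170.0 to 8753 ± 5.93 (1.43 ± 0.12, adjusted p = 1.94e-05), against 2763 and 7943 in wild type in air. AT2G39980 rose from 1921 ± 199 to 12397 ± 58.3 (2.68 ± 0.14, adjusted p = 3.46e-07), above the 3684 of wild type in air, and AT5G40590 from 146 ± 7.91 to 1658 ± 18.8 (3.37 ± 0.22, adjusted p = 2.56e-06). The peroxidase genes AT5G19890, AT1G49570 and AT3G49960 rose by 3.31 ± 0.22, 2.62 ± 0.20 and 1.64 ± 0.17, and CYP718 rose by 3.95 ± 0.31. Of 117 called probe sets 108 were higher and 9 lower, and 53 of the higher and 4 of the lower had 1 gene. Of 12 lists 3 were called: textbook ethylene-induced genes (adjusted p = 1.34e-05, and 0.0319 with an estimated correlation), the ethylene pathway (adjusted p = 0.0111, but adjusted p = 0.129 with an estimated correlation) and root hair expansins (adjusted p = 0.0111, but adjusted p = 0.244 with an estimated correlation). Here too the called pathway gene was RTE1, a member of the textbook list. The root hair list was not called without ein2 air 2 (0.137) or ein2 ethylene 1 (0.0582), and the cell wall expansion list was called without wild-type ethylene 1 (0.0187) or 2 (0.0189). Members called over all genes numbered 2 of 3 textbook, 1 of 2 pathway and 0 of 2 root hair genes, and 2, 1 and 2 when adjusted over the list alone. The 55 class III peroxidase genes shifted upward (adjusted p = 2.42e-05, but adjusted p = 0.238 with an estimated correlation), with 3 higher, 0 lower and 42 at a positive change. Without ein2 air 1 or 2 the calls numbered 51 and 48, without ein2 ethylene 1 or 2 50 and 40, and without wild-type ethylene 1 or 2 195 and 199. They numbered 34 without a variance trend, 458 (367 higher and 91 lower) when only the compared groups were fitted and 292 with array weights. Without ein2 ethylene 1 the split was 41 and 9.

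The extent to which each mutant kept the wild-type response was measured over the 2298 probe sets called in wild type. In ein5, 2008 of them (87.4%) had the same sign, against 58.0% of uncalled probe sets of similar level, and 299 were called the same way. In ein2, 1370 (59.6%) had the same sign, against 50.9%, and 75 were called the same way with 9 called the opposite way. By direction, of the 869 rises 722 kept their sign in ein5 and 574 in ein2, with 147 and 74 called, while of the 1429 falls 1286 kept their sign in ein5 and 796 in ein2, with 152 and 1 called. Median changes over the rises were 0.76 in wild type, 0.28 in ein5 and 0.17 in ein2, and over the falls -0.82, -0.31 and -0.04; the wild-type medians are inflated because the probe sets were chosen in wild type. The 51 probe sets called higher in all 3 genotypes, 28 of them with 1 gene, included RTE1, ARL, AT2G39980, AT5G40590, AT5G19890, AT1G49570, AT3G49960 and CYP718. Independent lists of these sizes would share 4.13 rises between wild type and ein2 and 6.72 between wild type and ein5, against the 74 and 147 observed. All calls used 1 spread per probe set for all groups, although the wild-type replicates differed more than the mutant ones. With only the compared groups fitted, wild type had 813 calls on ethylene, ein5 331 and ein2 458. Numbers of calls are therefore not sizes of response.

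**Figure D2:**
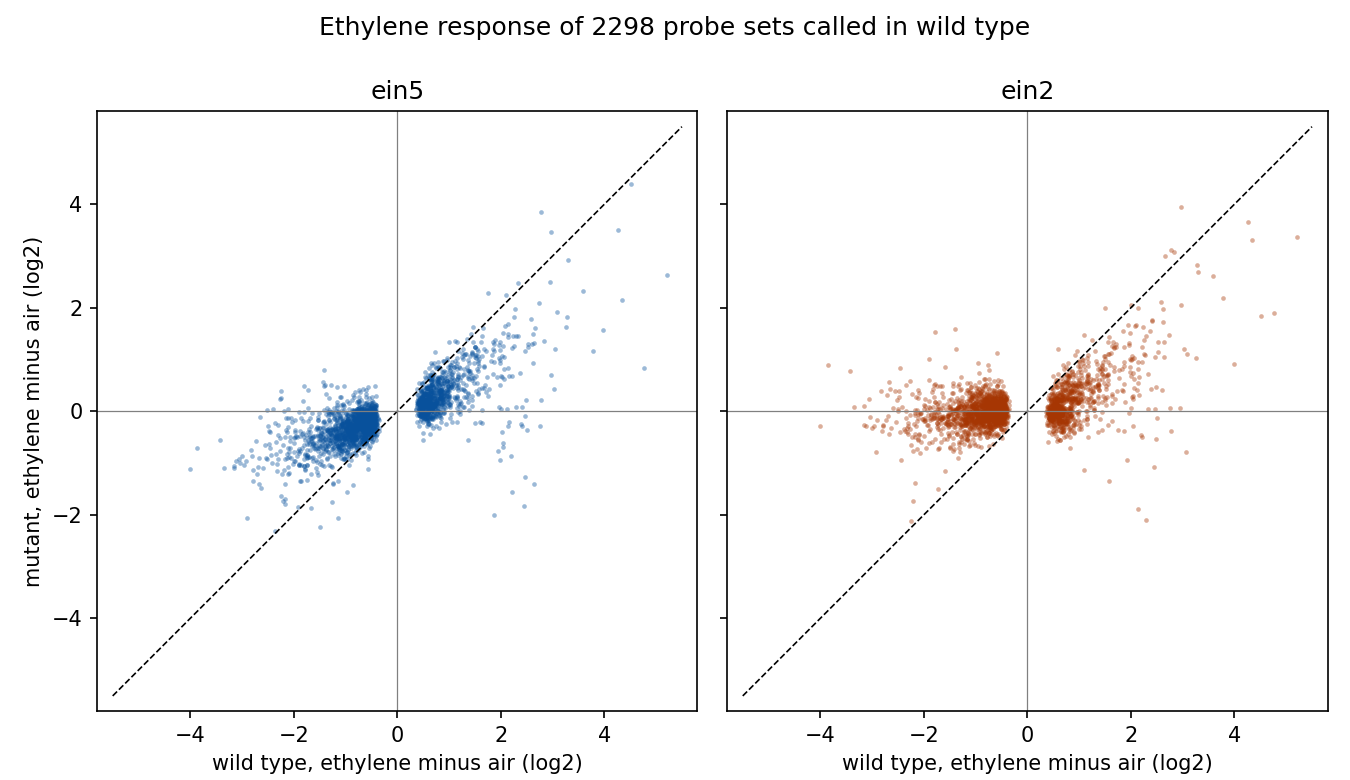
Ethylene response (log2, ethylene minus air) in ein5 (left panel) and ein2 (right panel) against that in wild type for the 2298 probe sets called in wild type; each point is 1 probe set and the dashed line marks equal responses. In ein5 87.4% of the points and in ein2 59.6% lie on the same side of 0 as in wild type, and the median change of the wild-type rises is 0.28 in ein5 and 0.17 in ein2.

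The difference between the ein5 and wild-type responses was tested directly. The fall of 3 GDSL lipase genes was smaller in ein5: AT1G75900 went from 12577 to 1510.2 in wild type and from 7403 to 3693 in ein5, a difference of 2.04 ± 0.17, adjusted p = 0.000112, and AT1G29660 and AT3G50400 differed by 2.14 ± 0.19 and 1.90 ± 0.26. AT5G13900 (2.25 ± 0.20, adjusted p = 0.000134) and TBL37 of the trichome birefringence-like family (1.76 ± 0.16, adjusted p = 0.000134) differed in the same direction. The rise was smaller in ein5 for AT5G40590 (-2.58 ± 0.31, adjusted p = 0.00158) and for the peroxidase genes AT5G19890 (-2.19 ± 0.31, adjusted p = 0.00527) and AT5G64120 (-1.19 ± 0.16, adjusted p = 0.00441). Of the textbook ethylene-induced genes none was called over all genes and 2 were when adjusted over the list alone, RTE1 (-0.67 ± 0.17, adjusted p = 0.103) and ARL (-0.57 ± 0.17, adjusted p = 0.191, or 0.04996 without wild-type ethylene 1). That list was the only fixed one of 12 called (adjusted p = 0.0211, but adjusted p = 0.235 with an estimated correlation), and it was not called without ein5 air 1 (0.0548), wild-type air 1 (0.0574), wild-type ethylene 1 (0.0533) or wild-type ethylene 2 (0.0564). The list of LEA genes, of which 10 of 36 fell in wild type with a list adjusted p = 0.325 at an estimated correlation, differed with a positive sign (adjusted p = 7.36e-05, but adjusted p = 0.217 with an estimated correlation; median 0.40). In total 121 probe sets were called, 98 positive and 23 negative. Of the 2298 wild-type calls 119 differed in ein5, 23 of the rises and 96 of the falls. Leaving out an array changed the count to 58 and 57 (ein2 air 1 and 2), 61 and 62 (ein2 ethylene 1 and 2), 80 and 29 (ein5 air 1 and 2), 46 and 40 (ein5 ethylene 1 and 2), 79 (wild-type air 2) and 402 (wild-type ethylene 1). The split was 223 positive and 179 negative without wild-type ethylene 1 and 87 and 51 without wild-type air 1. The count was 20 (13 and 7) without a variance trend, 26 when only the compared groups were fitted and 188 without dim probe sets.

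The corresponding test was made for ein2. SWEET17, which fell in wild type, lay at 3533 ± 198 in ein2 air and 4376 ± 163 in ein2 ethylene, so that the responses differed by 3.03 ± 0.31, adjusted p = 0.000102. HOS3-1, AT5G13900, AT3G50400, AT1G75900 and AT1G29660 differed in the same direction by 4.22 ± 0.53, 3.43 ± 0.20, 2.94 ± 0.26, 2.93 ± 0.17 and 2.68 ± 0.19. The expansin gene EXPA8 and the ACC oxidase gene AT1G12010, both lower on ethylene in wild type, differed by 1.33 ± 0.20 and 1.93 ± 0.30 (adjusted p = 0.00214 and 0.00232). The rises of GH9B12 (-1.97 ± 0.36, adjusted p = 0.0071) and AT5G40590 (-1.84 ± 0.31, adjusted p = 0.0044) were smaller in ein2. RTE1, at -0.63 ± 0.17, adjusted p = 0.0532, and ARL, at -0.15 ± 0.17, adjusted p = 0.741, did not differ past the threshold. In total 854 probe sets were called, 638 positive and 216 negative, of which 314 and 104 had 1 gene. Of the 1429 wild-type falls 573 differed in ein2, and of the 869 rises 181. No fixed list was called by camera, with 1 of 12 at an unadjusted p under 0.05. With values as deposited the split was 534 positive and 306 negative. Without ein2 air 1 or 2 there were 403 and 336 calls, and without ein2 ethylene 1 or 2 438 and 332. A fit without a variance trend gave 243 and a fit of the compared groups alone 536.

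The ethylene responses of ein5 and ein2 were then compared with each other. AT3G54580 went from 5085 to 2426 in ein5 and from 1504 to 2675 in ein2, a difference of -1.86 ± 0.28, adjusted p = 0.0457. AT2G22510 went from 5594 to 2746 in ein5 and from 4605 to 7042 in ein2 (-1.63 ± 0.22, adjusted p = 0.0232), and AT2G16630 and AT3G06750 differed by -1.04 ± 0.16 and -0.99 ± 0.16. These 4 were the genes among 12 called probe sets, which all had the more negative response in ein5; 2366 had an unadjusted p under 0.05, where 1137 were expected without any difference. No fixed list was called by camera, and 0 of 12 had an unadjusted p under 0.05. None of the 12 was called by limma on leaving out any mutant array. The calls numbered 0 and 1 without ein2 air 1 or 2, the 1 not being among the 12, 0 and 0 without ein2 ethylene 1 or 2, 0 and 0 without ein5 air 1 or 2, and 0 and 0 without ein5 ethylene 1 or 2. The 4 genes were not called in any of these fits, with adjusted p of 0.111 to 0.287, while 1667 to 2109 probe sets had an unadjusted p under 0.05. The count was 41 and 44 without wild-type air 1 or 2 and 88 and 86 without wild-type ethylene 1 or 2. It was 0 by limma without a variance trend (2017 at an unadjusted p under 0.05), 4 after quantile normalization, with an offset of 64 or with the replicate block, and 7 with values as deposited. It rose to 301 (71 positive and 230 negative) when only the mutant arrays were fitted, 194 (52 and 142) with array weights and 62 (7 and 55) without dim probe sets.

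Because the series concerns a role of the EIN5 exoribonuclease after transcription, ein5 and wild type were compared in air. PAP85, a seed cupin gene, lay at 1614 ± 141 in ein5 and 316 ± 173 in wild type (2.40 ± 0.28, adjusted p = 0.00104), and the LEA gene M17 at 981 ± 89.5 and 246 ± 53.1 (1.94 ± 0.24, adjusted p = 0.00129). AT3G19430 and AT1G50060 were higher by 1.42 ± 0.17 and 1.42 ± 0.16. UGT71C1, a glucosyltransferase gene, was lower at 2746 ± 636 against 7416 ± 1147 (-1.44 ± 0.17, adjusted p = 0.000909), as were AT3G18170 (-1.85 ± 0.21, adjusted p = 0.000909) and AT4G16563 (-1.19 ± 0.15, adjusted p = 0.00149). The 9 seed storage, oil body and cupin genes were higher as a list (adjusted p = 0.00591, but adjusted p = 0.254 with an estimated correlation), 3 of them called. The camera call of the 36 LEA genes was lost with an estimated correlation (adjusted p = 0.41), after quantile normalization (0.0904) and with the replicate block (0.0529). It was also lost on leaving out any ein2 array, either wild-type ethylene array, ein5 air 1 or wild-type air 1. Of the 36 genes 6 had an unadjusted p under 0.05. Of 66 microRNA target genes 7 were measured and named. Of these 1 was lower and 0 higher, and 1 was lower when adjusted over the list alone (list adjusted p = 0.376, median -0.22). Of 24 RNA decay genes 7 were measured and named. None of them was called by limma, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.5, median -0.13). No fixed list was called by camera, with 2 of 12 at an unadjusted p under 0.05, and the root hair list was called at 0.025 without wild-type air 2. Of 1320 called probe sets 463 were higher and 857 lower, but the split was 733 and 732 after quantile normalization and 727 and 640 with values as deposited. Without ein5 air 2 there were 46 calls and without ein5 air 1 807, without wild-type air 1 or 2 834 and 641, without ein2 air 1 or 2 865 and 867, and without wild-type ethylene 1 or 2 2196 and 2197. The count fell to 5 when only the compared groups were fitted and to 18 without a variance trend. Of the 20 genes named by the rule 7 were called in every leave-one-out fit, and each lost its call in at least 1 alternative.

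The ein2 mutant was compared with wild type in air in the same way. M17 was higher at 3966 ± 80.3 against 246 ± 53.1 (3.94 ± 0.24, adjusted p = 7.99e-07), the LEA gene AT5G66780 at 8464 ± 652 against 939 ± 172 (3.16 ± 0.23, adjusted p = 5.33e-06) and PAP85 at 2165 ± 208 against 316 ± 173 (2.82 ± 0.28, adjusted p = 7.97e-05). ATOEP16-2 was higher by 3.59 ± 0.37 and AT1G04560 by 2.88 ± 0.16. Of the 36 LEA genes 16 were higher and 0 lower, 30 with a positive change (adjusted p = 3.8e-18, and 0.00984 with an estimated correlation), and of the 9 seed storage, oil body and cupin genes 5 were higher (adjusted p = 7.9e-11, and 0.0187 with an estimated correlation). RTE1 (-1.21 ± 0.12, adjusted p = 6.84e-05) and ARL (-1.29 ± 0.12, adjusted p = 3.69e-05) were lower, together with the peroxidase genes AT1G49570 (-1.40 ± 0.20) and AT3G49960 (-1.24 ± 0.17). Of 12 lists 3 were called, each lower in ein2: the ethylene pathway (adjusted p = 0.00056, but adjusted p = 0.051 with an estimated correlation), textbook ethylene-induced genes (adjusted p = 0.000845, but adjusted p = 0.051 with an estimated correlation) and root hair expansins (adjusted p = 0.00648, but adjusted p = 0.206 with an estimated correlation, and 0.112 without wild-type air 1). Members called over all genes numbered 2 of 3 textbook, 1 of 2 pathway and 1 of 2 root hair genes, and 2, 2 and 2 when adjusted over the list alone. Both genes of the root hair specific list were negative as well, 1 of them called (adjusted p = 0.000781, and 0.038 with an estimated correlation). Of 616 called probe sets 282 were higher and 334 lower. Without ein2 air 1 or 2 there were 160 and 198 calls, without wild-type air 2 359, and without wild-type ethylene 1 or 2 986 and 979. The count was 123 (83 higher and 40 lower) without a variance trend and 265 (138 and 127) when only the compared groups were fitted. The majority also turned to 358 higher and 333 lower after quantile normalization, 323 and 287 without wild-type air 1 and 180 and 179 without wild-type air 2.

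**Figure D3:**
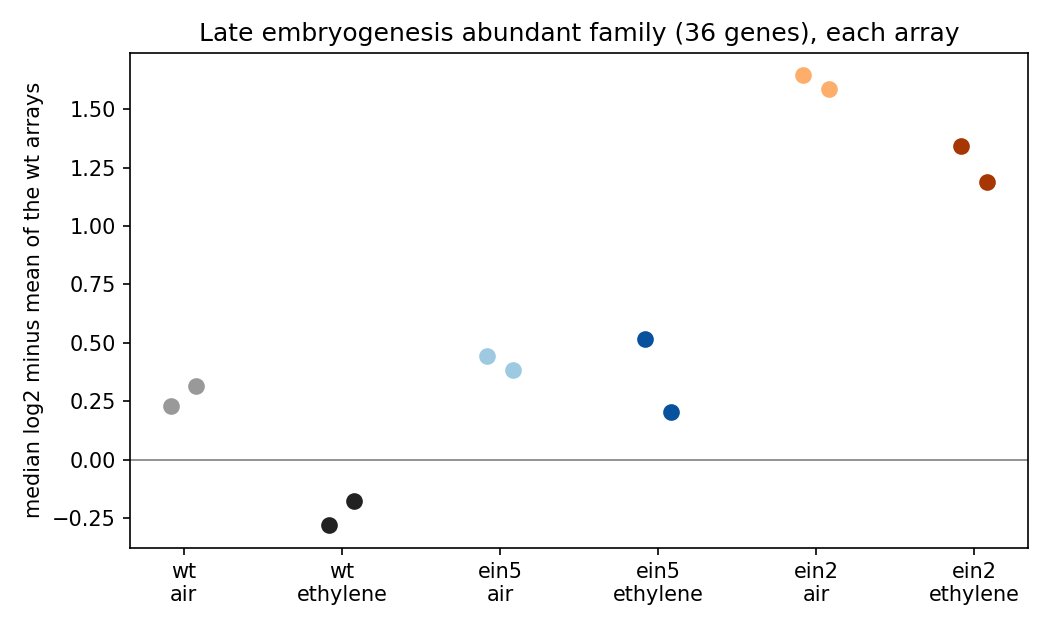
Median log2 level of 36 LEA genes on each of the 12 arrays, minus the mean of the 4 wild-type arrays; each point is 1 array. The 4 ein2 arrays lie between 1.19 and 1.64, the ein5 arrays between 0.20 and 0.52 and the wild-type arrays between -0.28 and 0.32.

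Overlap between the mutants in air was measured against their common wild-type arrays. Calls in the same direction numbered 192, 80 higher and 112 lower in both mutants, and 7 were opposite. Seed-related genes were among the shared rises, with M17 at 981 in ein5, 3966 in ein2 and 246 in wild type, and PAP85 at 1614, 2165 and 316. Independent lists of these sizes would share 18.3, and 50 simulations of mutants without any effect against the same control arrays shared 0.02 on average and at most 1. The first value leaves out the shared controls and the second the effects, so neither is the overlap of lists that hold effects and share controls. The covariance of the log2 changes across probe sets was 0.137, against 0.0904 in the simulations, a difference of 0.0461. Their correlation across probe sets, which are not independent replicates, was 0.474, against 0.4998 in the simulations. The simulated arrays all had the same spread per probe set, although the wild-type air arrays differed more from each other than the mutant replicates did. With the controls split, a fit chosen after the data had been seen, ein5 against wild-type air 1 and ein2 against wild-type air 2 had 70 calls in the same direction and 8 opposite, where independent lists would share 8.41. With the control arrays exchanged the numbers were 62 and 7, against 6.62. The covariance was 0.0379 and 0.0414 in these splits and the correlation 0.0979 and 0.108. Each split leaves 1 control array per mutant, assumed to vary like the other groups, and part of the 192 may come from the shared controls. The overlap was 18 without ein5 air 2, 50 and 60 without ein2 air 1 or 2, 124 and 126 without ein2 ethylene 1 or 2, 113 without wild-type air 2, and 382 and 379 without wild-type ethylene 1 or 2.

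Set against each other in air, ein5 had the higher level of RTE1 (change 0.83 ± 0.12, adjusted p = 0.00168) and ARL (1.28 ± 0.12, adjusted p = 4.19e-05), and also of AT1G50060 (2.48 ± 0.16, adjusted p = 6.05e-06) and AT1G65570 (1.87 ± 0.19, adjusted p = 9.64e-05). Seed-related genes were lower in ein5 than in ein2: the LEA genes AT4G21020 (-2.39 ± 0.30) and AT5G66780 (-2.11 ± 0.23), the oil body gene AT2G25890 (-2.20 ± 0.16) and the beta-glucosidase gene BGLU19 (-2.23 ± 0.26), which went from 4134 in ein2 to 868 in ein5. Of the LEA genes 16 were lower and 1 higher (adjusted p = 7.8e-14, and 0.02 with an estimated correlation). The camera call of the seed storage, oil body and cupin list was lost with an estimated correlation (adjusted p = 0.139). Of its 9 genes 4 had an unadjusted p under 0.05. Of 12 lists 3 were called: the ethylene pathway (adjusted p = 0.00278, but adjusted p = 0.0766 with an estimated correlation) and textbook ethylene-induced genes (adjusted p = 0.00239, but adjusted p = 0.0766 with an estimated correlation) higher in ein5, and cell wall expansion lower (adjusted p = 0.0104, but adjusted p = 0.481 with an estimated correlation, 0.0533 without ein5 air 2 and 0.0509 after quantile normalization). Textbook genes called over all genes numbered 2 of 3 and pathway genes 1 of 2, and 2 and 2 when adjusted over the list alone; for cell wall expansion the numbers were 1 of 7 and 2. Of 722 called probe sets 278 were higher and 444 lower in ein5, or 396 and 341 with values as deposited. The count was 151 and 158 without ein2 air 1 or 2, 476 without ein2 ethylene 1, 299 and 117 without ein5 air 1 or 2, and 1245 and 1246 without wild-type ethylene 1 or 2. It was 124 without a variance trend and 1681 with array weights.

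In ethylene, ein5 differed from wild type both in genes of the ethylene response and in seed-related genes. RTE1 was lower in ein5 (-1.05 ± 0.12, adjusted p = 0.000195), as were the peroxidase genes AT5G19890 (-2.65 ± 0.22), AT5G64120 (-1.85 ± 0.11) and AT1G49570 (-1.61 ± 0.20). AT5G13900 and AT1G75900, which ethylene lowered in wild type, were higher in ein5 (2.19 ± 0.14, adjusted p = 1.9e-06, and 1.28 ± 0.12, adjusted p = 5.36e-05). M17 lay at 1405 ± 504 against 197 ± 26.5 (2.69 ± 0.24, adjusted p = 3.92e-05), and the LEA gene AT5G66780, PAP85 and LEA18 were higher by 2.19 ± 0.23, 1.97 ± 0.28 and 1.71 ± 0.19. Of the LEA genes 13 were higher and 0 lower (adjusted p = 2.36e-08, but adjusted p = 0.0647 with an estimated correlation). Of 12 lists 3 were called, all lower in ein5. Textbook ethylene-induced genes had an adjusted p of 0.011, but adjusted p = 0.186 with an estimated correlation and 0.0509 without wild-type ethylene 1. The ethylene pathway and root hair lists both had an adjusted p of 0.0404, but adjusted p = 0.235 and 0.365 with an estimated correlation, 0.0777 for both without wild-type ethylene 1, 0.133 for both without wild-type ethylene 2, and 0.0551 and 0.0971 without ein5 ethylene 2; after quantile normalization they had 0.133 and 0.0679. Members called over all genes numbered 2 of 3 textbook, 1 of 2 pathway and 0 of 2 root hair genes, and 2, 1 and 2 when adjusted over the list alone. Of 1156 called probe sets 489 were higher and 667 lower, against 688 and 582 after quantile normalization and 711 and 501 with values as deposited. Without ein5 ethylene 1 or 2 there were 336 and 364 calls, and without wild-type ethylene 1 or 2 2539 and 610, the last split into 370 higher and 240 lower. There were 317 (168 and 149) without a variance trend, 254 when only the compared groups were fitted and 686 with array weights.

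The same comparison was made for ein2. ATOEP16-2 was higher in ein2 at 1105 ± 196 against 15.3 ± 7.41 (adjusted p = 6.1e-07), and no size is given because the wild-type level lies under the offset of 16. The LEA gene AT5G66780 was higher at 5636 ± 908 against 217 ± 62.4 (4.62 ± 0.23, adjusted p = 2.43e-08), and M17 and the oil body gene AT2G25890 by 3.99 ± 0.24 and 3.49 ± 0.16. The GDSL lipase gene AT1G29660, lowered by ethylene in wild type, was higher by 3.85 ± 0.14, adjusted p = 1.74e-09, and EXPA8 by 1.48 ± 0.14, adjusted p = 9.87e-06. IAGLU lay at 4242 ± 625 in ein2 and 20442 ± 1237 in wild type (-2.27 ± 0.16, adjusted p = 6.1e-07), and RTE1, ARL, GH9B12 and XTH26 were lower with changes of -1.85 ± 0.12, -1.43 ± 0.12, -2.30 ± 0.25 and -2.35 ± 0.43. Of the LEA genes 18 were higher and 1 lower (adjusted p = 6.84e-12, and 0.0292 with an estimated correlation). Of 12 lists 3 were called, all lower in ein2: textbook ethylene-induced genes (adjusted p = 3.61e-05, and 0.0392 with an estimated correlation), the ethylene pathway (adjusted p = 0.000485, and 0.0455 with an estimated correlation) and root hair expansins (adjusted p = 0.0382, but adjusted p = 0.372 with an estimated correlation, 0.0854 without ein2 ethylene 2, 0.114 without wild-type ethylene 2 and 0.0565 after quantile normalization). Members called over all genes numbered 2 of 3 textbook, 2 of 2 pathway and 2 of 2 root hair genes, and 2, 2 and 2 when adjusted over the list alone. The photosynthesis list was called without wild-type ethylene 1 (0.0444) and the cell wall expansion list without wild-type ethylene 2 (0.0282). In all 2246 probe sets were called, 1456 higher and 790 lower in ein2. The count was 1363 and 1131 without ein2 ethylene 1 or 2, 1438 without a variance trend and 1267 when only the compared groups were fitted. The split was 1299 and 929 after quantile normalization, 1272 and 1038 with values as deposited and 1786 and 579 without wild-type ethylene 2.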

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

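The tests below of a wild-type admixture, low ein2 air arrays and chamber effects were chosen after the result was seen. So were those of whole-family LEA levels, the shift removed by quantile normalization and seed-stage RNA on all ein2 plates. Only the pair of LEA tests without the genes named by the rule was written before its result, on a list written after the leading genes had been seen. In this part the ± after a median or a difference of medians is a standard error over probe sets or genes. These share the same arrays and are not independent replicates, so the ± leaves out the spread between arrays.

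Responses to ethylene differed between genotypes by a test of the difference itself. Between ein5 and wild type 121 probe sets were called by limma, but 20 without a variance trend, 26 when only the compared groups were fitted and 29 to 402 on leaving out 1 array. Between ein2 and wild type 854 were called, but 243 and 536 in these fits and 332 to 1174 on leaving out 1 array. Between ein5 and ein2 12 were called, none of them without a variance trend (0 calls by limma, 2017 at an unadjusted p under 0.05) or on leaving out any mutant array (0 or 1 calls by limma, 1667 to 2109 at an unadjusted p under 0.05). A fit of the mutant arrays alone called 301. The textbook ethylene-induced genes responded less in ein5 than in wild type (camera, adjusted p = 0.0211 with a median difference of -0.67 over 3 genes, but adjusted p = 0.235 with an estimated correlation). That call was lost without ein5 air 1 (0.0548), wild-type air 1 (0.0574), wild-type ethylene 1 (0.0533) or wild-type ethylene 2 (0.0564).

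The first pattern was that 74 probe sets rose on ethylene in both wild type and ein2, RTE1 and ARL among them, with median rises of 1.66 and 1.16, and that the responses differed past the threshold for 12 of the 74. A chamber or handling effect common to all ethylene plates stays open for the whole of the rise in ein2: over the 51 probe sets that rose in all 3 genotypes the wild-type rise exceeded that in ein2 by a median of 0.54 ± 0.11, which such an effect together with a response to ethylene in wild type also predicts. RNA of ethylene-treated wild type in the ein2 ethylene arrays stays open, since the wild-type rises had moved a median of 18.5% of the way to the wild-type ethylene level and the wild-type falls 10.8%, a difference of 7.76 ± 3.95 percentage points; a first version gave 13.4 ± 2.94 points and would have argued against it, but it took only rises also called in ein2, which raises their share by selection, and was replaced after its result was seen. Low ein2 air arrays alone also stay open: against wild-type air the median log2 change of the 74 probe sets was -0.90 in ein2 air and 0.36 ± 0.09 in ein2 ethylene, with 60 of them higher, which is not past the limit of 0.2 by 3 standard errors. A remaining ethylene response of the ein2 allele used is a candidate explanation that was not tested.

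The second pattern was the higher level of LEA genes in ein2, where the medians of the 36 genes against the mean of the wild-type arrays were 1.64 and 1.58 in air and 1.34 and 1.19 in ethylene, compared with 0.20 to 0.52 on the ein5 arrays. Scaling of the arrays as the whole cause is argued against, since quantile normalization removed a median of 0.0618 ± 0.0116 from the difference between ein2 and wild type in air over the 36 genes and left 0.99 ± 0.25, although over the 29 genes not named by the rule it left 0.38 ± 0.23, which by itself is not past the limit of 0.2 by 3 standard errors. Ungerminated seed on only some ein2 plates would leave at least 1 ein2 array near wild type. Over the whole family the lowest ein2 array lay at 1.19 ± 0.26 and the wild-type arrays at -0.28 to 0.32. The seed storage, oil body and cupin medians were 2.40, 2.45, 2.14 and 2.37 on the ein2 arrays and -0.84 to 0.45 on the wild-type arrays. On the ein5 arrays they lay between these, at 0.96 to 1.31. On these lists no ein2 array lay near wild type. The lists were written after the leading genes had been seen, and the whole family includes genes named for groups that do not overlap. Their medians were therefore partly fixed by that choice and do not decide the question. Over the 29 genes the lowest ein2 array lay at 0.45 ± 0.24, not past that limit, so the explanation stays open. Slower germination or more seed-stage RNA on all ein2 plates also stays open, because the LEA and seed list medians above the limit on 4 of 4 ein2 arrays only restate the pattern; ein2 air 1, the only sample whose text gives 3 days of growth, had an LEA median of 1.64, and ein2 air 2 had 1.58. A direct effect of the ein2 lesion on these transcripts was not tested and cannot be told apart from a difference in developmental stage, since every ein2 array carries both the lesion and the higher LEA level.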

How the results depend on the processing

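Of the alternatives below, the values as deposited, the split of the control arrays and the 5 added gene lists were chosen after the data had been seen; the others were planned.

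No call of a named gene, list member or list reversed its direction in any alternative run. Dropping the trend of variance with intensity moved every count, to 1323 in wild type, 50 in ein5 and 34 in ein2 (ethylene against air), 20 (ein5 minus wild type), 243 (ein2 minus wild type), 0 (ein5 minus ein2), 18 and 123 (ein5 and ein2 against wild type in air), 317 and 1438 (the same in ethylene) and 124 (ein5 against ein2 in air). The limma count of 0 had 2017 probe sets at an unadjusted p under 0.05. Fitting only the compared groups gave 813 in wild type, 458 in ein2, 26, 536 and 301 for the 3 differences of responses in the same order, 5 and 265 for ein5 and ein2 against wild type in air, and 254 and 1267 in ethylene; this fit has fewer arrays to estimate the spread. Array weights, which gave the wild-type ethylene arrays 0.519 and the wild-type air arrays 0.837, gave 1309 in wild type, 867 in ein5, 292 in ein2, 194 for ein5 minus ein2, 686 for ein5 against wild type in ethylene and 1681 for ein5 against ein2 in air. Without dim probe sets, which leaves fewer to test, ein5 minus wild type had 188 and ein5 minus ein2 62. The latter had 4 after quantile normalization, 4 with an offset of 64 and 7 with values as deposited. The share of wild-type calls with the same sign in ein5 was 85.7% after quantile normalization, and over the 200 probe sets with the smallest p in wild type it was 98.5% in ein5 and 75.5% in ein2. With the wild-type air arrays split between the mutants the overlap of their calls in air was 70 or 62 instead of 192, with 1 control array for each. List calls over all comparisons numbered 21, but 5 with an estimated correlation. The main fit gave all groups 1 spread per probe set, although median replicate differences were 0.32 and 0.25 in wild type and 0.19 to 0.21 in the mutants. Counts from wild type and from the mutants therefore do not compare as sizes of response. Apart from these constructions, the cause of each moved count was not tested.

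Leaving out 1 array, where the lone array of a group is assumed to vary like the other groups, gave these lowest and highest counts of calls. Ethylene against air had 1589 to 2846 in wild type, 106 to 576 in ein5 and 40 to 199 in ein2. The differences of responses had 29 to 402 (ein5 minus wild type), 332 to 1174 (ein2 minus wild type) and 0 to 88 (ein5 minus ein2). Against wild type, ein5 had 46 to 2197 in air and 336 to 2539 in ethylene, and ein2 160 to 986 and 1131 to 2425; ein5 against ein2 in air had 117 to 1246. The share with the same sign was 78.1% to 92.0% in ein5 and 53.0% to 66.1% in ein2, the overlap of the mutants in air 18 to 382, and the number of list calls 18 to 21.

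With the replicate number as a replicate block, ein5 minus ein2 had 4 calls instead of 12, and the other counts stayed within 1.5 times: 2300, 367, 112, 112, 851, 1310, 611, 1158, 2225 and 695 in the order of the first list without that comparison, with 21 list calls. Deviations of same-numbered arrays from their group means correlated at -0.0437 to 0.0734, so no strong common shift tied to the replicate number was seen. Batches that do not follow that number would not show in this measure.

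Among single genes, calls of named genes were lost 65 times without a trend, 36 with only the compared groups, 5 after quantile normalization, 3 with an offset of 64, 2 with values as deposited, 2 with the replicate block and 195 over all leave-one-out fits, where 2145 held. List members not among them lost 64, 44, 8 and 4 calls (no trend, compared groups, quantile normalization, values as deposited), 15 with array weights, 2 with the replicate block and 259 over the leave-one-out fits, which gained 96. Fixed lists lost 16 calls with an estimated correlation, 5 after quantile normalization and 22 on leaving out an array, which gained 7; added lists lost 24, 2 and 24 there and 1 with the replicate block, and gained 13 on leaving out an array. The list members not among the named genes also gained calls in other settings. They gained 12 after quantile normalization, 10 with values as deposited, 17 with array weights and 5 with the replicate block. Removal of dim probe sets gave 27 gains, the compared groups alone 17, and offsets of 1 and 64 gave 4 and 1. Signal over background limits the dim end: 3.75% to 5.98% of the values of an array were at or under the offset of 16.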

Other observations

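The tests of added lists in this part were chosen after the leading genes had been seen. Class III peroxidase genes, enzymes of the cell wall and apoplast, stood lower in ein5 than in wild type on ethylene. Of 55 such genes 9 were lower and 2 higher, or 17 and 3 when adjusted over the list alone (camera, adjusted p = 0.00245, but adjusted p = 0.351 with an estimated correlation; median -0.25). AT5G64120 went from 5293 ± 66 in air to 17139 ± 2001 in ethylene in wild type (1.69 ± 0.11, adjusted p = 4.76e-07), and lay at 4734 ± 514 in ein5 and 8289 ± 185 in ein2 on ethylene. GAT1_2.1 and AT2G41090 were also lower in ein5 than in wild type on ethylene, with log2 changes of -1.85 ± 0.18 and -1.45 ± 0.14. The list of peroxidase genes further had a more negative response in ein5 than in ein2 (adjusted p = 0.0018, but adjusted p = 0.386 with an estimated correlation; median -0.37), with 0 single genes called by limma and 9 at an unadjusted p under 0.05.

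GDSL lipase genes were higher in ein2 than in wild type on ethylene, with 14 higher and 1 lower of 72 (adjusted p = 0.000214, but adjusted p = 0.121 with an estimated correlation). AT1G29660 lay at 4421 ± 883 in wild-type air and 531 ± 20.1 in wild-type ethylene, and at 9871 ± 90.2 and 7872 ± 613 in ein2. In ein2 ethylene against ein2 air none of these genes was called by limma, with 8 at an unadjusted p under 0.05, and the list's adjusted p was 0.247. The response of the family was more negative in ein5 than in ein2 (adjusted p = 0.00835, but adjusted p = 0.386 with an estimated correlation; median -0.26), with 0 genes called by limma over all genes, 15 at an unadjusted p under 0.05, and 1 positive and 4 negative when adjusted over the list alone. The 9 seed storage, oil body and cupin genes were higher in ein2 than in wild type on ethylene, 5 of them called (adjusted p = 5.37e-07, but adjusted p = 0.0534 with an estimated correlation), and in ein5 likewise with 5 (adjusted p = 1.98e-06, but adjusted p = 0.0647 with an estimated correlation).

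The level of CYP718 in air was 603 ± 81 in wild type, 119.9 ± 67.4 in ein5 and 57.9 ± 12.9 in ein2. On ethylene it reached 4836 ± 57.8, 1384 ± 76.8 and 1121 ± 107 in the same order. The log2 rise was 2.98 ± 0.31, 3.46 ± 0.31 and 3.95 ± 0.31. In ein5 and ein2 it started from a lower air level and ended below the wild-type ethylene level. No test of a difference between these rises is given here.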
